A study of Mus musculus with 2 samples.

How the data were processed

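Single cells from lung tumours of KP and KPI mice were measured with a 3' droplet kit that tags each molecule, 1 library per genotype, per the labels. Each library pooled 5 tumours from each of 2 animals, and the labels give no map from cells to animals or tumours. CD31-positive cells, which include endothelium, TER-119-positive red cells and Annexin V-positive dying cells were removed before 10000 cells were loaded per library, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode, not normalised, in matrices limited to barcodes taken as cells. Cell Ranger and the build GRCm38 are named in the submitters' processing notes; the version and the annotation release are not given in the sources used here. The matrices had 31055 features, of which 30934 had their identifier in GENCODE M21, from which chromosome, start and end were taken. The features for tdTomato and EGFP held 0 UMIs in both libraries.

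Barcodes with at least 300 detected genes and at most 15% mitochondrial UMIs were kept, which left 7143 of 7893 in KP and 7862 of 8817 in KPI. Scrublet, run per library in scanpy 1.11.5, marked 0 doublets in both with its automatic threshold, so the rule fixed beforehand took over: the highest scores were removed at a rate of 0.8% per 1000 barcodes, which marked 522 barcodes (6.61%) in KP and 625 (7.09%) in KPI. The 6658 KP and 7267 KPI cells left were normalised to 10000 UMIs per cell and log-transformed for clustering only. Of 2500 variable genes, 2422 were used after removal of Xist, Tsix and mitochondrial, ribosomal, haemoglobin and receptor segment genes (Y-linked genes stayed in), with 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at a resolution of 1, which gave 27 clusters over both libraries together with no batch correction. The marker lists, the gene lists, the rule for named genes and the settings, with a first set of alternatives, were fixed before the data were examined. A cluster took the class whose markers stood highest in it. It stayed unnamed with fewer than 20 cells, with fewer than 3 detected markers, with more markers of another class than of its own among its top 10 genes, with a median UMI count, in the library that held most of its cells, under that of the library divided by 3, or with a median Malat1 share under 0.3%. These limits for naming were set after the data were seen. The one on Malat1 kept out cluster 5, and the one on UMIs kept out cluster 9, which had the epithelial markers Sftpc, Sftpa1, Ager and Cxcl15 among its leading genes. Cluster 13, whose leading genes included the epithelial marker Krt18, scored highest for airway secretory cells and stayed unnamed because its KPI cells had a median of 730.5 UMIs and no marker of that class was among its top 10 genes. The 79 KP cells of cluster 13 had a median of 4655 UMIs. Class names are therefore rebuilt here and stand for cells like those classes. Epithelial alveolar cells include tumour cells and any normal alveolar cells.

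Counts were summed per class and library and given as CPM of the class total. A sum has an exact Poisson interval, a share an exact Clopper-Pearson interval, a difference of shares a Newcombe interval and a ratio of CPM values an exact conditional binomial interval, all at 95% and all for counting error only. Computation used python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. No test was made between genotypes because each had 1 library. Genes were named by a rule of size in classes with at least 100 cells in each library, which left 6 classes. The rule asked for a summed count of at least 100, a UMI in at least 10% of the cells of the class in the library with the higher CPM, a class CPM of at least 0.5 times that library's own CPM, and a ratio of at least 2-fold with an interval that left out 1. The 10 largest ratios per direction were named in epithelial cells and the 5 largest in each other class. Mitochondrial, ribosomal, haemoglobin, receptor segment, predicted (Gm and Rik), Xist, Tsix and Y-linked genes, and markers of other classes in epithelial cells, were left out of naming. Members of the fixed lists and Prkci, Prkcz, Kras and Trp53 were named at any size. A list member was measured with a summed count of at least 20 and counted as higher or lower at 1.5-fold or more with an interval that left out 1. A gene with 0 counts in 1 library was given as a bound at 3 counts over the class.

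The epithelial lists were AT2 identity, AT1 identity, transitional or high-plasticity state, airway secretory, gastric and gut endoderm, mesenchymal, Wnt targets, Notch, YAP TEAD targets, cell cycle, MHC class I, MHC class II, interferon response, checkpoint ligands, chemokines and cytokines, glycolysis and hypoxia, lipid and sterol synthesis, immediate early and heat shock, p53 targets, NRF2 targets, MAPK output, and atypical PKC and polarity. Further lists for T cells, macrophages and monocytes, and neutrophils were fixed with them, and 5 of the lists above were also taken in the immune classes. A list's median log2 ratio was set against 10000 random lists of the same size matched over 50 bins of mean expression, as a description of these libraries.

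The ratio step was tested on simulated counts drawn for the real genes of each class. They were Poisson draws around KP levels, with no variation between cells, tumours or animals. The rates below thus hold for counting error only and give no rate of false calls between genotypes. In the epithelial comparison, 1 of 58 genes changed 1.5-fold, 43 of 44 changed 2.5-fold, 50 of 50 changed 4-fold and 48 of 48 changed 8-fold met the rule, as did 0 of 15107 unchanged genes, and 95.2% of intervals held the true ratio. For B cells, the class with fewest KP cells, 31 of 6203 unchanged genes met it. Of 1000 simulated epithelial lists over 18819 genes with no change, 5.9% fell outside the central 95% of random lists, and 100% of lists shifted by 0.5 lay above it. Medians of UMIs per cell differed between libraries in some classes, from 11736 in KP to 21566 in KPI for macrophages and monocytes and from 51304 to 37394 for epithelial cells.

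The first set of alternatives held a stricter cell filter (at least 500 genes and at most 10% mitochondrial UMIs), no cell filter with doublets still removed, no doublet removal, resolutions of 0.5 and 2, a denominator of non-epithelial cells, TMM scaling of the class sums (edgeR 4.0.16 in R 4.3.3), the mean of per-cell CPM, cells thinned to 1000 UMIs (5335 KP and 6807 KPI cells, with 1323 and 460 too shallow), subtraction of free RNA with the library-wide sum as its profile and its share estimated from markers of other classes, minimum summed counts of 20 and 300, and epithelial cells without a UMI of Mki67 or Top2a. Alternatives chosen after the data were seen were a denominator of named cells, the low-Malat1 cluster counted as epithelial, cells with Y-linked and no Xist UMIs, and epithelial cells without the KPI-only cluster. Fragments of transcripts shared by near-identical genes, such as Hspa1a and Hspa1b or members of the H2-Q and Xlr families, can be split or dropped by the counting, so their values are uncertain.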

Results

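Lung tumours of 2 mouse genotypes were profiled by droplet-based single-cell RNA sequencing with unique molecular identifiers (UMIs). KP mice carried an activated Kras allele and floxed Trp53 alleles, and KPI mice carried floxed alleles of Prkci in addition, the gene of the atypical protein kinase C iota. Recombination was started with an adenovirus that expressed Cre under the surfactant protein C promoter, which is active in alveolar type 2 (AT2) cells of the lung. Tumours were taken at about 30 weeks from KP and about 40 weeks from KPI animals, 5 from each of 2 animals, so that 1 library per genotype pooled the cells of 10 tumours. The KP library held 7893 barcodes and 147094926 UMIs, with a median of 4937 UMIs per barcode, and the KPI library held 8817 barcodes and 157369008 UMIs, with a median of 6523. After filtering, 6658 KP and 7267 KPI cells were kept. With 1 library per genotype no test was possible, and age differed along with genotype. Xist, the transcript of the inactive X chromosome, had 19 UMIs in KP and 53173 in KPI epithelial alveolar cells. Part of the KPI cells thus appear female, so that sex differed in part along with genotype too. The 95% intervals of shares, levels and ratios cover counting error only, and those of list medians the spread over genes. None covers the spread between animals. List medians are medians of log2 ratios of CPM, the count of a gene scaled to the class total, KPI over KP, with a sign-test interval over genes, beside the central 95% of 10000 random lists matched on size and expression.

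The level of the targeted gene in the class that holds the tumour cells was examined first. Prkci (ENSMUSG00000037643, chromosome 3, 30995747 to 31052959, GRCm38) was at 94.3 CPM (92.4 to 96.2) in KP and 71.0 CPM (69.3 to 72.8) in KPI epithelial alveolar cells, 1.33-fold lower in the KPI library (interval 1.29 to 1.37). Prkcz, the other atypical protein kinase C gene, was 1.14-fold lower (1.10 to 1.19). Kras was at 329 CPM in KP and 321 CPM in KPI, and Trp53 was 1.60-fold higher in the KPI library (1.51 to 1.70). In T cells the Prkci level was 12.4 CPM (9.09 to 16.6) in KP and 9.46 CPM (7.52 to 11.7) in KPI, a difference within counting error. The counts come from the 3' end of transcripts, and the sources used here do not name the deleted Prkci exon. A 3' tag outside the deleted part checks nothing, so these levels neither show nor exclude recombination. With each cell thinned to 1000 UMIs the log2 ratio of Prkci was -0.17, with an interval from -0.51 to 0.17.

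The make-up of the tumours was compared next, as shares of kept cells. Lymphocytes made up more of the KPI library: B cells were 1.52% (1.24 to 1.84) of KP and 11.8% (11.1 to 12.6) of KPI cells, a difference of 10.3 percentage points (9.51 to 11.1). T cells were 5.83% and 13.8%, a difference of 8.002 points (7.03 to 8.98), and NK cells 0.150% and 1.46%, a difference of 1.31 points (1.03 to 1.62). Plasma cells were 0.105% and 2.05%. Macrophages and monocytes were 2.25% (1.91 to 2.64) of KP and 7.21% (6.63 to 7.83) of KPI cells, 4.96 points higher (4.27 to 5.66), and conventional dendritic cells 0.391% and 1.09%, 0.697 points higher (0.416 to 0.990). The size of these differences depended on the processing: that of T cells was 4.795 points at a clustering resolution of 2.0 and 12.2 points in cells with Y-linked and no Xist UMIs, and that of NK cells was 3.08 points at a resolution of 0.5. In cells with Y-linked and no Xist UMIs macrophages and monocytes were 7.68 points and dendritic cells 0.279 points higher.

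Neutrophils were the most abundant named class of both libraries, at 30.2% (29.1 to 31.3) of KP and 27.0% (26.0 to 28.1) of KPI cells, a difference of -3.12 points (-4.62 to -1.62). Epithelial alveolar cells, which hold tumour cells and any normal alveolar cells, were 23.5% and 22.7%, a difference of -0.774 points with an interval that held 0 (-2.18 to 0.627). Fibroblasts were 4.03% and 2.26%, and ciliated cells 0.150% and 0.440%. Among named immune cells alone, neutrophils were 74.6% of KP and 41.9% of KPI, T cells 14.4% and 21.4%, and B cells 3.75% and 18.3%. Shares can be set by the preparation, which removed CD31-positive, TER-119-positive and Annexin V-positive cells and loaded 10000 cells per library, and by depth, since the median UMI count per barcode was lower in the KP library. Cells left without a class were 31.9% of KP and 10.1% of KPI: clusters 5, 9 and 13 held 8.16%, 22.5% and 1.19% of KP and 2.31%, 0.509% and 7.24% of KPI cells, and cluster 22 held 6 KP cells. Clusters 9 and 13 had epithelial markers such as Sftpc and Krt18 among their leading genes, so that the epithelial shares depend on leaving them out. Over named cells only, the difference was -9.25 points for epithelial cells and -14.2 points for neutrophils. In cells with Y-linked and no Xist UMIs the epithelial difference was -20.5 and the neutrophil share difference -4.98 points. This selection was uneven: 1613 of 2124 unnamed KP cells but 175 of 1566 KP epithelial cells held neither marker. It also left out the 1015 of 1653 KPI epithelial cells that held Xist and no Y-linked UMIs. All share differences in such cells depend in part on it.

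**Figure D1:**
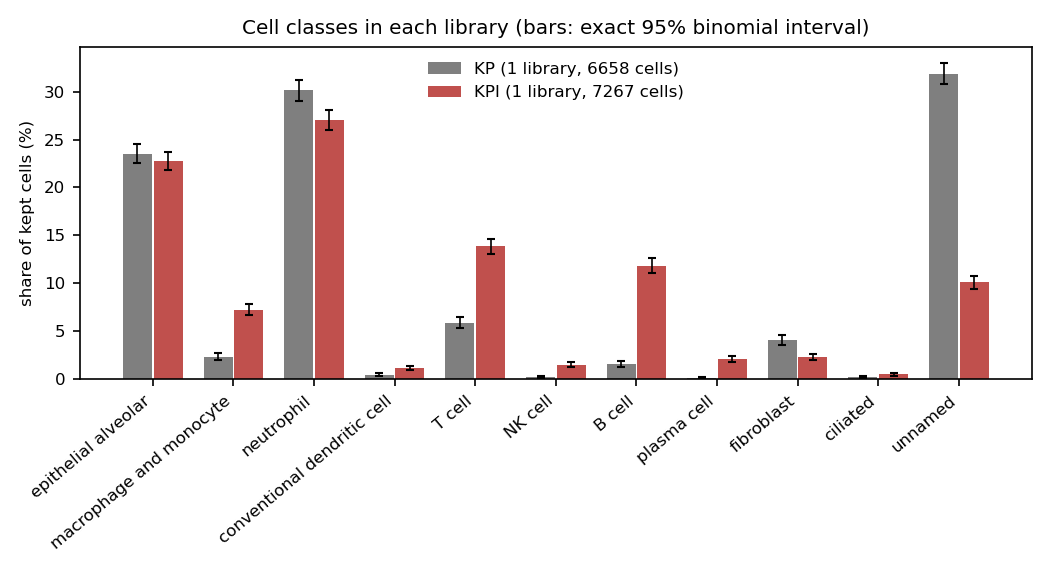
Share of kept cells in each class (percent, y axis) in the KP and KPI libraries, 1 library each, with exact binomial intervals as error bars that cover counting error only. B cells were at 1.52% in KP and 11.8% in KPI, T cells at 5.83% and 13.8%, and epithelial alveolar cells at 23.5% and 22.7%.

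The state of the epithelial cells was compared with lists of lineage genes. Genes of AT2 identity were lower in the KPI library: 17 of 20 measured members were at least 1.5-fold lower and 0 were higher, with a list median of -0.96 (-1.43 to -0.72; random lists -0.15 to 0.22). The surfactant protein gene Sftpc was at 30215 CPM in KP and 7599 CPM in KPI, 3.98-fold lower (3.97 to 3.99), and Sftpa1 was 4.73-fold lower (4.69 to 4.76). The lamellar body lipid transporter gene Abca3 was 2.70-fold lower (2.63 to 2.77), and Nkx2-1, the lung lineage transcription factor, 1.79-fold lower (1.76 to 1.83). Of the alveolar type 1 (AT1) genes, 11 of 16 were lower, with a median of -1.08 (-2.00 to -0.34; random lists -0.21 to 0.25). Pdpn was 18.8-fold lower (16.7 to 21.3), Hopx 2.71-fold (2.65 to 2.78) and Ager 2.25-fold (2.22 to 2.27).

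Genes of the transitional or high-plasticity state, a partly dedifferentiated alveolar state, were higher in the KPI library. Of 19 members, 10 were at least 1.5-fold higher and 0 lower, with a median of 0.59 (0.42 to 1.12; random lists -0.15 to 0.24). Tm4sf1 was 3.53-fold higher (3.40 to 3.66), the claudin gene Cldn4 2.64-fold (2.59 to 2.70), the urokinase receptor gene Plaur 2.57-fold (2.52 to 2.63) and the keratin gene Krt19 2.06-fold (2.04 to 2.08). Cell cycle genes had a median of 0.33 (0.21 to 0.63; random lists -0.25 to 0.25), with 6 of 22 higher. Ube2c was 2.12-fold higher (1.96 to 2.29) and Cdk1 2.07-fold (1.89 to 2.28), while Mki67 was at 14.7 CPM in KP and 18.2 CPM in KPI. With each cell weighted equally the cell cycle median was 0.16.

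Different clusters held the epithelial cells of the 2 libraries. Clusters 3, 2 and 4 held 42.7%, 31.4% and 22.3% of KP epithelial cells, whereas cluster 26, with no KP cell, held 71.7% of KPI epithelial cells. Cluster 26 scored 1.72 for epithelial alveolar and 1.11 for airway secretory cells. The other epithelial clusters scored from 2.49 to 3.37 for epithelial alveolar cells. No marker of its class was among the top 10 genes of cluster 26, so that its alveolar name is less certain. In that KPI-only cluster the Y-linked transcripts were at 2.52% of their KP epithelial level and Xist, the transcript of the inactive X chromosome, at 845 CPM. In the other KPI epithelial cells Y-linked transcripts were at 109% of the KP level. Without the KPI-only cluster the AT2 median was -0.17 (-0.45 to 0.30), the AT1 median -0.40 (-0.67 to -0.01) and the transitional median 0.10 (-0.13 to 0.33). The intervals of the AT2 and transitional medians thus held 0 in the remaining 467 KPI epithelial cells. In the same cells the cell cycle median was 1.38 (0.80 to 1.81). Those cells shared clusters with KP cells by expression, so that a likeness to KP was partly set by this choice. Inside the KPI-only cluster alone, the AT2 median against KP was -1.81, the transitional median 0.71 and the cell cycle median -0.46. Cluster 10, with the cell cycle genes Ube2c, Cenpf and Top2a among its leading genes, held 57 KP and 46 KPI epithelial cells. It lay outside the KPI-only cluster, so that both cell cycle medians depend on the clustering.

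Antigen presentation genes were lower in KPI epithelial cells. Of the MHC class I list, 13 of 17 members were lower and 0 higher, with a median of -1.15 (-1.43 to -0.66; random lists -0.24 to 0.25). B2m, the light chain of class I molecules, was at 225 CPM in KP and 79.1 CPM in KPI, 2.85-fold lower (2.77 to 2.93), H2-K1 was 2.51-fold lower (2.46 to 2.56) and the peptide transporter gene Tap1 2.80-fold lower (2.49 to 3.14). Of the MHC class II list, 7 of 10 members were lower and 2 higher, with a median of -1.40 and an interval that held 0 (-1.55 to 1.89). Cd74, the invariant chain, was 2.62-fold lower (2.59 to 2.65) and Ciita, the class II transactivator, 3.23-fold lower (2.93 to 3.57), while Ctss was 3.71-fold higher (3.28 to 4.21). Without the KPI-only cluster the medians were -0.33 (-0.70 to 0.02) for class I and -0.15 (-0.49 to 1.91) for class II. After subtraction of free RNA the class II median was -2.80.

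Interferon response genes were lower as well: 12 of 24 measured members were lower and 0 higher, with a median of -0.64 (-1.28 to -0.28; random lists -0.25 to 0.28). Rsad2, which encodes viperin, was 13.2-fold lower (8.32 to 22.3) and Isg15 2.52-fold lower (2.25 to 2.81), while Irf1 was at 22.7 CPM in KP and 25.2 CPM in KPI. The median was -0.48 without the KPI-only cluster and -0.12 (-0.76 to 0.27) in cells thinned to 1000 UMIs. Genes of chemokines and cytokines went the other way, with 12 of 20 higher, 2 lower and a median of 0.71 (-0.06 to 1.49; random lists -0.22 to 0.25). The neutrophil attractant genes Cxcl5 and Cxcl1 were 5.27-fold (5.05 to 5.50) and 4.43-fold (4.19 to 4.69) higher, Csf2 was at 6.20 CPM in KP and 17.4 CPM in KPI, and Tgfb1 was 2.04-fold lower (1.94 to 2.15). This median was 0.38 without the KPI-only cluster, and 0.17 at its lowest under the alternatives chosen after the data were seen. For checkpoint ligands the median was 0.18 (-0.16 to 0.67), inside the range of random lists. Cd274, which encodes PD-L1, was 1.57-fold higher (1.41 to 1.75), and Cd47 was at 129 CPM in KP and 116 CPM in KPI.

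**Figure D2:**
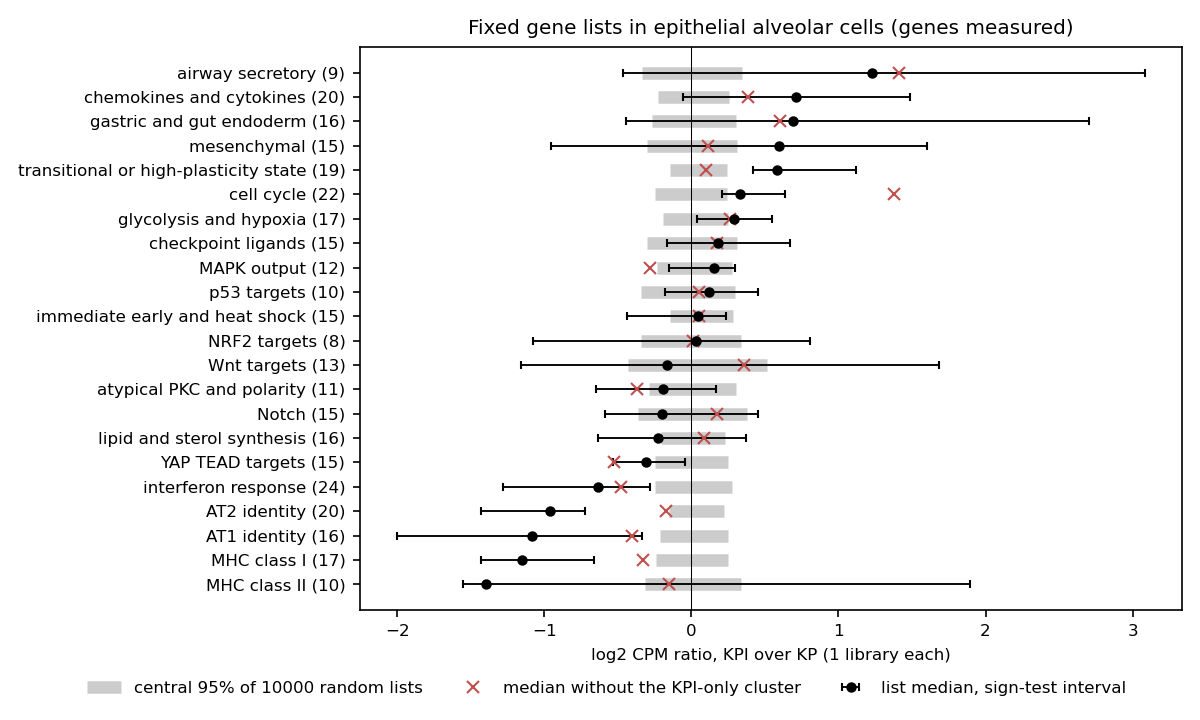
Median log2 CPM ratio (x axis, KPI over KP, 1 library each) of each fixed gene list (y axis, measured members in brackets) in epithelial alveolar cells, with sign-test intervals as error bars, the central 95% of 10000 random lists as grey bars and the median without the KPI-only cluster as crosses. The AT2 median lay at -0.96, and at -0.17 without that cluster, while the cell cycle median lay at 0.33 and 1.38.

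By the fixed rule of size, 1359 genes were at least 2-fold apart in epithelial alveolar cells, 598 higher and 761 lower in the KPI library. Without the KPI-only cluster the number was 636, of which 357 were shared, and in thinned cells it was 159. Of the 10 named as higher, Fgb, the fibrinogen beta chain gene, was at 0.134 CPM in KP and 90.6 CPM in KPI, 677-fold higher (396 to 1272). The membrane mucin gene Muc3 had 1 UMI in KP and 1682 in KPI, a log2 ratio of 10.88 (8.40 to 16.19). Nr1h5, a nuclear receptor gene, was 119-fold higher (71.7 to 213), the steroid dehydrogenase gene Hsd3b2 298-fold (157 to 653) and Tmem252 397-fold (285 to 570.1). The developmental regulators Prox1 and Eya4 were 61.0-fold (44.6 to 85.6) and 107-fold (83.7 to 139.8) higher, and Soga3, the adenylate cyclase gene Adcy8 and the keratin gene Krt12 138-fold (63.3 to 379), 106-fold (76.9 to 151) and 66.6-fold (44.6 to 104).

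Among the named lower genes, Fgf9, a fibroblast growth factor gene, was 79.9-fold lower in the KPI library (38.5 to 199.5) and Bmpr1b, a bone morphogenetic protein receptor gene, 17.4-fold (13.8 to 22.4). The X-linked genes Xlr4a and Xlr were 48.1-fold (27.3 to 93.6) and 25.5-fold (15.01 to 47.0) lower. Myrip, which links myosin to Rab proteins, was 92.3-fold lower (42.2 to 253), Tecrl 41.3-fold (25.6 to 71.2), Nrgn 25.7-fold (17.7 to 38.6), Kcnf1 17.4-fold (10.6 to 30.9) and Tmem91 17.4-fold (12.9 to 23.9), and Pdpn, given above, completed the 10. All 20 genes stayed at least 2-fold apart in the same direction without the KPI-only cluster, but the ratios of several shrank: the log2 ratio of Eya4 was 6.75 with it and 1.76 without it, and that of Soga3 7.11 and 2.57. In cells with Y-linked and no Xist UMIs Prox1 was at a log2 ratio of 0.87, and 17 of the 20 were still at least 2-fold apart with an interval that left out 0. Without the KPI-only cluster the log2 ratio of Fgb was 5.14, against 9.40 with it, and those of Muc3 and Hsd3b2 were 9.30 and 7.71.

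T cells were compared in 388 KP and 1005 KPI cells. Naive and central memory genes were higher in the KPI library, with 5 of 9 members higher, 0 lower and a median of 0.60 (0.16 to 0.85; random lists -0.19 to 0.16). S1pr1, the receptor for lymphocyte egress, was 2.11-fold higher (1.89 to 2.35), and the transcription factor gene Lef1 1.81-fold (1.68 to 1.95). Genes of checkpoint receptors and exhaustion were lower, with 5 of 13 lower, 0 higher and a median of -0.53 (-0.80 to -0.12; random lists -0.18 to 0.12). Pdcd1, the PD-1 gene, was 1.89-fold lower (1.68 to 2.13) and Havcr2 1.75-fold (1.45 to 2.10), whereas Ctla4 was 1.33-fold higher (1.27 to 1.39). At a clustering resolution of 2.0 this median was -1.18.

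Cytotoxic genes went both ways, with 3 of 12 higher, 3 lower and a median of -0.08 (-0.79 to 1.01). That median was -0.86 at resolution 2.0 and 0.27 in cells with Y-linked and no Xist UMIs. Ccl5 was 2.02-fold higher (1.96 to 2.08), and Tnf and Ifng were 2.51-fold (2.10 to 2.99) and 1.77-fold (1.57 to 2.00) lower. The type 17 and gamma-delta median was -0.68 (-1.14 to 0.54), with Trdc 2.01-fold lower (1.80 to 2.23), and the tissue resident median -0.32 (-1.505 to -0.15), with Cxcr6 2.84-fold lower (2.62 to 3.08). The regulatory T cell median was 0.14 (-0.28 to 0.77), with Foxp3 1.41-fold higher (1.19 to 1.68). Cell cycle genes had a median of 0.43 (0.14 to 0.68), which was 0.07 without doublet removal. Interferon response genes were lower, 11 of 23, with a median of -0.63 (-1.23 to -0.33; random lists -0.26 to 0.09). In T cells the MHC class I median was -0.23 (-0.27 to 0.03), the MHC class II median 0.67 (0.02 to 1.40), and that of immediate early and heat shock genes -0.27 (-0.67 to 0.06).

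By the rule of size, 129 genes were at least 2-fold apart in T cells, 39 higher and 90 lower in the KPI library; in thinned cells the number was 36. Gzma, a granule protease gene, was 7.86-fold higher (6.86 to 9.03), and the NK receptor gene Klra9 8.69-fold (5.61 to 14.2). Cluster 17, which had as many NK as T cell markers among its leading genes, held 2.32% of KP and 15.3% of KPI T cells, and the log2 ratio of Gzma turned to -0.11 at a resolution of 2.0 and to -0.11 without doublet removal. Cd200 was 6.38-fold (4.67 to 8.94), Cpm 6.003-fold (5.19 to 6.98) and Mgst2 3.53-fold (2.53 to 5.03) higher. Dscaml1 was 28.7-fold lower (18.2 to 47.8), the phosphodiesterase gene Pde4d 5.55-fold (5.28 to 5.84), the interferon-induced gene Ifitm1 8.92-fold (7.02 to 11.5), the semaphorin gene Sema6d 5.82-fold (4.78 to 7.13) and Gpr160 5.78-fold (3.89 to 8.77). The log2 ratio of Ifitm1, -3.16, was -0.75 without doublet removal.

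B cells, 101 in KP and 859 in KPI, also had lower interferon response genes in the KPI library, 7 of 11 with a median of -1.28 (-1.93 to -0.29; random lists -0.50 to 0.31). Irf7 was 3.804-fold lower (2.39 to 5.91) and Stat1 1.96-fold lower (1.42 to 2.66). MHC class II genes had a median of 0.44 (0.18 to 0.59; random lists -0.18 to 0.19), with H2-Aa at 2751 CPM in KP and 3961 CPM in KPI. The medians of MHC class I, cell cycle and immediate early and heat shock genes were -0.15 (-0.32 to 0.16), -0.03 (-2.22 to 0.77) and -0.28 (-0.92 to 0.25). Pde4d was 15.2-fold lower (13.5 to 17.2), the heat shock genes Hspa1a and Hspa1b were 4.60-fold (3.92 to 5.38) and 4.71-fold (3.84 to 5.75) lower, and the interferon-induced Ifi213 and Slfn8 6.02-fold (4.38 to 8.22) and 4.04-fold (2.59 to 6.16). Pde4d was at least 2-fold lower in all 6 classes compared, with log2 ratios from -3.93 to -1.05, and from -4.73 to 7.90 after subtraction of free RNA. Gpr132 was 12.2-fold higher (6.95 to 23.6) in B cells. Slc15a2, Il5ra, Pld4 and Adprhl2 rested on 1 or 2 KP UMIs, with log2 ratios of 4.94 (2.45 to 10.24), 4.19 (2.32 to 7.24), 3.06 (1.18 to 6.12) and 2.98 (1.10 to 6.04), and in thinned cells Pld4 turned to -0.34, Slc15a2 was at 0.95 and Il5ra at 0.89. Of the 10 named B cell genes, 5 were there still at least 2-fold apart in the same direction with an interval that left out 0. In all, 186 genes were at least 2-fold apart, 103 higher and 83 lower in KPI.

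Macrophages and monocytes, 150 in KP and 524 in KPI, had higher levels of the C1q genes, which start the classical complement pathway, in the KPI library. C1qb was 2.82-fold higher (2.56 to 3.103), C1qa 2.49-fold (2.28 to 2.73) and C3ar1 2.83-fold (1.91 to 4.35), whereas Cfb was 1.81-fold lower (1.27 to 2.54). The complement median was 1.30 with an interval that held 0 (-0.85 to 1.499; random lists -0.33 to 0.26). MHC class II genes had a median of 0.58 (0.38 to 0.72; random lists -0.17 to 0.24), 5 of 10 being higher and 0 lower, with Ctss 1.83-fold higher (1.77 to 1.89). The median of the inflammatory list was -0.25 (-1.51 to 0.13), with Tnf 2.86-fold (2.55 to 3.20) and Il6 2.90-fold (2.47 to 3.40) lower and Il1b at 1339.8 CPM in KP and 1417 CPM in KPI; it was 0.36 in thinned cells. That of the alternatively activated list was 0.55 (-0.03 to 2.48), with Ccl17 3.29-fold higher (3.07 to 3.53). The lipid associated list went both ways, with a median of -0.35 (-0.98 to 0.82): Spp1 was 2.15-fold lower (2.08 to 2.23) and Apoe 1.76-fold higher (1.68 to 1.85).

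In the same cells the interferon response median was -0.34 (-0.75 to 0.00), the MHC class I median -0.00 (-0.24 to 0.16), the cell cycle median -0.28 (-0.43 to -0.05) and that of immediate early and heat shock genes -0.33 (-0.44 to 0.10). With each cell weighted equally the cell cycle median was 0.0023, and that of immediate early genes was 0.11. By the rule of size, 411 genes were at least 2-fold apart, 241 higher and 170 lower in KPI, against 964 with each cell weighted equally, 69.0% of them higher, and 116 in thinned cells, 81.0% of them higher. Fbp1, which encodes a gluconeogenic phosphatase, had 0 KP UMIs. Against a floor of 3 counts over the class Fbp1 was 102-fold higher, with a lower limit of 82.8-fold. Rnase2a was 18.2-fold higher (10.6 to 34.3) and Asgr2 17.8-fold (6.89 to 65.7), while Retnla and Adamtsl5, with 3 and 1 KP UMIs, had log2 ratios of 5.96 (4.41 to 8.24) and 4.53 (2.02 to 9.84), the latter turning to -0.85 in thinned cells. There Asgr2 was at 0.81, against 4.15 in all UMIs, and 7 of the 10 named genes were still at least 2-fold apart in the same direction with an interval that left out 0. Marco, a scavenger receptor gene of alveolar macrophages, was 7.21-fold lower (6.60 to 7.88), Ear6 205-fold (86.3 to 638), Sntg1 15.9-fold (11.3 to 22.5), Kcnj15 6.87-fold (5.21 to 9.08) and Atp11b 5.75-fold (5.32 to 6.21). Cluster 16, which scored highest for alveolar macrophages, held 45.3% of KP and 15.3% of KPI cells of this class. Cluster 18, which scored highest for monocyte-derived macrophages, held 18.7% and 51.9%. The C1q genes were on the marker list of the latter and Marco on that of the former, though C1qa and C1qb led cluster 16 too. Cluster 21, which also scored highest for alveolar macrophages, held 36.0% and 32.8%. Cluster 16 had medians of 2243 KP and 2891 KPI UMIs per cell, against 25683 and 32874 in cluster 21. Cluster 16 therefore weighed little in the summed counts. A change of mix may give part of the ratios of Marco and the C1q genes, but how much was not tested.

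Neutrophils, 2008 in KP and 1965 in KPI, had lower interferon response genes in the KPI library. Of 22 measured members, 19 were lower and 0 higher, with a median of -2.04 (-3.39 to -1.31; random lists -0.10 to 0.18). Rsad2 was at 283 CPM in KP and 11.4 CPM in KPI, 24.8-fold lower (20.6 to 30.1). Isg15, a ubiquitin-like modifier, was 4.95-fold lower (4.57 to 5.37), Ifit1 14.1-fold (10.4 to 19.5), the interferon-induced GTPase gene Gbp2 8.77-fold (6.85 to 11.4) and Cxcl10 3.57-fold (3.32 to 3.84). These genes were found in a minority of cells, such as Rsad2 in 14.1% of KP and 1.27% of KPI neutrophils. Ifit1 was found in 6.18% and 0.712%, and Isg15 in 26.2% and 13.5%. At a clustering resolution of 0.5, a neutrophil cluster with Rsad2, Isg15 and Ifit1 among its leading genes held 75 KP and 4 KPI cells. The MHC class I median was -0.23 (-0.66 to -0.11), with Nlrc5, its transactivator, 5.55-fold lower (4.01 to 7.84). The MHC class II median was 0.71 (-0.42 to 0.98), and 0.16 at its lowest under the alternatives fixed beforehand. Genes of tumour-associated neutrophils had a median of -0.21 (-0.42 to 0.27), with Siglecf at 165 CPM in KP and 199 CPM in KPI. Those of circulating neutrophils had a median of 0.09 (-0.45 to 0.73), which was -0.24 in cells with Y-linked and no Xist UMIs. Of the latter, the granule gene Camp was at 62.3 CPM in KP and 355 CPM in KPI, found in 2.29% and 4.07% of neutrophils. The granule gene Ltf was at 140.5 CPM in KP and 185 CPM in KPI, and Mmp8, another, at 135 and 54.1 CPM.

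The neutrophil medians of cell cycle and of immediate early and heat shock genes were 0.55 (0.17 to 1.15) and -0.35 (-0.47 to -0.04). The first was 0.24 in thinned cells. In cells with Y-linked and no Xist UMIs they were 0.14 and -0.09. By the rule of size, 90 genes were at least 2-fold apart in neutrophils, 22 higher and 68 lower in KPI. Gsr, the glutathione reductase gene, was at 1758 CPM in KP and 107 CPM in KPI, 16.5-fold lower (15.5 to 17.6), Arhgap31 11.2-fold (10.1 to 12.5) and the transcript of the Rosa26 locus, Gt(ROSA)26Sor, 13.1-fold (8.22 to 22.2). The organic anion transporter gene Slco1a6 had 741 UMIs in KP and 1 in KPI, a log2 ratio of -9.56 (-14.87 to -7.08). Npl was 107-fold higher (41.4 to 393), the retinol dehydrogenase gene Rdh12 18.3-fold (14.4 to 23.7), the fatty acid transporter gene Slc27a4 4.78-fold (3.75 to 6.16) and Noct 3.36-fold (3.02 to 3.74). Scgb3a1, a secretory airway gene, had 3 KP and 1098 KPI UMIs, a log2 ratio of 8.48 (6.93 to 10.76), and was higher in the KPI library in all 6 classes compared. Cluster 0 held 31.8% of KP and 16.0% of KPI neutrophils, and cluster 8 23.1% and 45.8%.

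**Figure D3:**
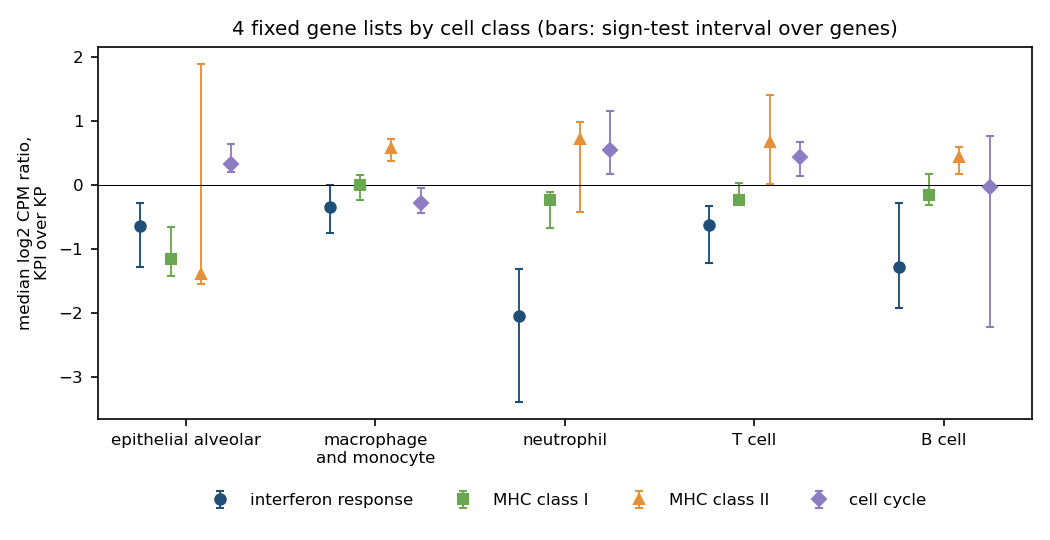
Median log2 CPM ratio (y axis, KPI over KP, 1 library each) of 4 fixed gene lists in 5 cell classes (x axis), with sign-test intervals over genes as error bars. The interferon response median was -2.04 in neutrophils, -1.28 in B cells, -0.63 in T cells, -0.64 in epithelial alveolar cells and -0.34 in macrophages and monocytes.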

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

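The values inside and without the KPI-only cluster and those in cells with Y-linked and no Xist UMIs were chosen after the data were seen; each result stands here because a direction differed between cell classes or because it lay in data outside the comparisons above. Cell cycle genes went different ways between classes: the median log2 ratio, KPI over KP, was 0.43 in T cells, 0.33 in epithelial alveolar cells and 0.55 in neutrophils, but -0.28 in macrophages and monocytes, where it was 0.0023 with each cell weighted equally. The epithelial median was -0.46 inside the KPI-only cluster and 1.38 without it. Cluster 10, with Ube2c, Cenpf and Top2a among its leading genes, held 57 KP and 46 KPI epithelial cells. It lay outside the KPI-only cluster but among the KP cells set against that cluster. Both values therefore depend on the clustering, and the direction in most KPI epithelial cells cannot be told from them. The T cell median was 0.07 without doublet removal, and the neutrophil median was 0.14 in cells with Y-linked and no Xist UMIs. The difference between classes was not tested.

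Xist, the transcript of the inactive X chromosome, stood at 462 CPM over the kept KPI cells and had 0 UMIs in the KP cells of 5 of the 6 classes compared, with 19 UMIs in KP epithelial cells. Y-linked transcripts of KPI cells were at 43.9% of the KP level in B cells, 55.0% in T cells, 47.7% in neutrophils, 67.4% in macrophages and monocytes, 38.5% in fibroblasts and 32.7% in epithelial alveolar cells.

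The cells left without a class were spread unevenly. Cluster 5, with a low share of the nuclear transcript Malat1, held 8.16% of KP and 2.31% of KPI cells. Cluster 9, with a median of 703.5 UMIs per KP cell, held 22.5% of KP cells, and cluster 13 held 1.19% of KP and 7.24% of KPI cells.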

How the results depend on the processing

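A value counted as stayed when it lay inside the 95% interval of the reported one, which covers counting error for genes and shares and the spread over genes for list medians, or, for a number of genes, within 1.5 times of it. It counted as reversed when its sign changed and the reported interval left out 0. Over the alternatives fixed beforehand, 107 of 131 values of the designed results stayed, 24 moved and 0 reversed; over those chosen after the data were seen, 30 of 50 stayed and 20 moved. Of single genes and other lists, 718 of 833 stayed, 107 moved and 8 reversed under the former, and 134 of 187 stayed, 52 moved and 1 reversed under the latter. The 7 share differences compared kept their direction under the alternatives run. Depth limits the values of small classes: KP held 101 B cells with 536909 UMIs in all, 150 macrophages and monocytes and 268 fibroblasts. No paired analysis was possible because each genotype had 1 library. The cause of the shifts was not tested, except that thinning and a higher minimum count leave fewer genes to compare.

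Share differences, KPI minus KP in percentage points, moved as follows. Over non-epithelial cells they were 6.39 for macrophages and monocytes, 10.3 for T, 1.69 for NK and 13.3 for B cells. Over named cells they were -9.25 for epithelial cells, -14.2 for neutrophils and 6.82 for T cells. In cells with Y-linked and no Xist UMIs they were -20.5 for epithelial cells, 7.68 for macrophages and monocytes, -4.98 for the neutrophil share difference, 0.279 for dendritic, 12.2 for T and 12.2 for B cells. The selection of such cells was uneven between classes, as given above. With no cell filter, T cells were at 5.40 and B cells at 9.25; T cells were at 5.62 without doublet removal and at 6.29 and 4.795 at resolutions of 0.5 and 2. NK cells were at 3.08 at 0.5, neutrophils at -5.32 with the stricter filter, and epithelial cells at -6.62 with the low-Malat1 cluster.

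The log2 ratio of Prkci was -0.33 with each cell weighted equally, -0.17 in thinned cells and -0.27 in cells with Y-linked and no Xist UMIs. In those last cells the epithelial medians were -0.20 for AT2, 0.012 for transitional and -0.40 for MHC class I genes. Without the KPI-only cluster they were -0.17, 0.10 and -0.33, and 1.38 for cell cycle genes. The cell cycle median was 0.16 with equal weights and 0.16 in thinned cells, where the interferon median was -0.12. Subtraction of free RNA gave -1.59 for MHC class I and -2.80 for class II.

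Of epithelial genes, 1359 were at least 2-fold apart, 159 in thinned cells (135 shared), 626 in cells with Y-linked and no Xist UMIs (363 shared) and 636 without the KPI-only cluster (357 shared), with 44.0%, 29.2% and 34.3% of them higher in KPI in all cells and under those last 2 settings. For macrophages and monocytes the number was 411, with 58.6% higher, against 964 (69.0%) with equal weights, 116 (81.0%) in thinned cells and 225 at a minimum count of 300. For T cells it was 129, with 30.2% higher, against 36 in thinned cells and 80 (41.3%) at a minimum of 300. Values reversed in this sense were the macrophage cell cycle median at 0.0023 with equal weights; Gzma in T cells at -0.11 without doublet removal and -0.11 at resolution 2; Gdf15 in fibroblasts at -0.44 at resolution 2 and -0.33 in cells with Y-linked and no Xist UMIs; and, in thinned cells, Pld4 in B cells at -0.34, Adamtsl5 in macrophages and monocytes at -0.85, and Ifit1 and Myrip in fibroblasts at 0.022 and 2.34. Medians whose reported interval held 0 changed sign too: among those that moved, airway secretory genes in epithelial cells were at -0.52 after subtraction of free RNA, MAPK output genes at -0.24 in cells with Y-linked and no Xist UMIs and -0.28 without the KPI-only cluster, inflammatory genes of macrophages and monocytes at 0.36 in thinned cells, and their immediate early and heat shock genes at 0.11 with equal weights and 0.18 in thinned cells.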

Other observations

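The tests on doublets, the female animal and loss of Prkci for the KPI-only cluster and the test of a germline variant for Rpl29 were chosen after the results were seen. Several endoderm and airway genes outside the alveolar lineage were higher in KPI epithelial cells. The gastric and gut endoderm list had 9 of 16 members higher and 3 lower, with a median of 0.69 (-0.44 to 2.70). That median was 0.39 at its lowest under the alternatives chosen after the data were seen. The transcription factor gene Onecut2 was 13.8-fold higher (13.3 to 14.2), the gut lectin gene Lgals4 6.32-fold (6.05 to 6.61) and Hnf4a 1.95-fold (1.89 to 2.02), while Gkn2 was 2.46-fold lower (2.42 to 2.49). Of the airway secretory genes Muc5b was 8.46-fold higher (8.05 to 8.90), and the list median was 1.23 (-0.47 to 3.08), or -0.52 after subtraction of free RNA. The mesenchymal median was 0.59 against a mean of 0.06, with Vim 3.82-fold (3.67 to 3.97) and Hmga2 3.32-fold (3.23 to 3.41) higher but Mmp14 3.83-fold lower (3.67 to 4.003). That median was 0.028 in cells with Y-linked and no Xist UMIs and 0.12 without the KPI-only cluster. Glycolysis and hypoxia genes had a median of 0.29 (0.04 to 0.55), with Pkm 1.70-fold higher (1.68 to 1.72). YAP TEAD targets had a median of -0.31 (-0.53 to -0.05), with Cyr61 1.76-fold lower (1.72 to 1.80), and lipid and sterol synthesis genes -0.23 (-0.63 to 0.37). The remaining epithelial medians had intervals that held 0: Wnt targets -0.17, Notch -0.20, immediate early and heat shock 0.04, p53 targets 0.12, NRF2 targets 0.03, MAPK output 0.15, and atypical PKC and polarity -0.19. Without the KPI-only cluster the median of MAPK output genes was -0.28, and those of Wnt targets, Notch and lipid and sterol synthesis genes were 0.35, 0.17 and 0.08.

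Fibroblasts, 268 in KP and 164 in KPI, had 363 genes at least 2-fold apart, 58 higher and 305 lower in KPI. Markers of other classes stood at 56.8% of their library-wide level in KP fibroblasts and 25.6% in KPI fibroblasts, against 12.7% and 11.9% in neutrophils. The cytokine gene Il11 was 6.14-fold higher (4.32 to 8.90), the growth factor genes Gdf15 and Bmp8a 5.32-fold (4.43 to 6.44) and 3.93-fold (2.82 to 5.52), Ly6d 17.7-fold (13.8 to 23.2) and Dnah12 8.16-fold (5.67 to 12.03). Slfn4 was 28.3-fold lower (12.8 to 77.8), the zinc transporter gene Slc39a8 14.3-fold (6.79 to 36.1) and Myrip 27.6-fold (10.6 to 102). Lypd6 and Ifit1, with 1 KPI UMI each, had log2 ratios of -6.39 (-11.71 to -3.89) and -6.16 (-11.48 to -3.65). These ratios depended on depth and clustering. In thinned cells 1 of the 10 named genes was still at least 2-fold apart in the same direction with an interval that left out 0, and 8 kept their sign: the log2 ratio of Myrip turned to 2.34, that of Lypd6 was -0.24 and that of Ly6d 1.17. At resolution 2.0 that of Gdf15 turned to -0.44.

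The KPI-only epithelial cluster held most of the KPI epithelial cells and had the lower AT2 genes. Doublets or unusually deep cells are argued against by its median UMI count, 0.927 times that of the other KPI epithelial cells. Its cells may come from 1 female KPI animal alone: Y-linked transcripts were at 2.52% of the KP epithelial level, against 109% in the other KPI epithelial cells. A gain of the chromosome 12 region around Ddx1 is a further hypothesis for part of its expression. Ddx1 was 40.8-fold (39.8 to 41.8), Nbas 27.5-fold (26.5 to 28.4) and Mycn 3.43-fold (3.26 to 3.61) above KP. Next to Mycn, Fam49a was 3.49-fold, 4921511I17Rik 19.2-fold and 4930519A11Rik 98.6-fold above KP, the last 2 with 17 and 2 KP UMIs. Smc6 and Fam84a, the next measured genes on either side of this stretch, were at 0.704 and 0.939 times KP. Kcns3, beyond Smc6, was 45.4-fold above KP too, with 12 KP UMIs. In the other KPI epithelial cells Ddx1 was at 2.81, Nbas at 1.56 and Mycn at 1.08 times KP. Ddx1 was higher in KPI in all 6 classes compared, such as 15.9-fold in neutrophils and 2.27-fold in B cells. Its lowest log2 ratio of the classes was -6.80 after subtraction of free RNA. Free RNA may thus give part of the Ddx1 level outside the KPI-only cluster, which was not tested for the other epithelial cells. The window of 5 genes centred on Ddx1 ranked 10 of 15170. Windows such as the keratin genes around Krt12, which can be switched on together without a gain, ranked higher. Ddx1 and Nbas were among the leading genes of this same cluster, so that the rank of their window cannot count for a gain. Loss of Prkci cannot be told apart from age, from sex or from differences between animals or tumours. The AT2 median of the other KPI epithelial cells was -0.17, and nothing shows which of those cells lost the gene.

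Interferon response genes were lower in neutrophils of the KPI library, where free RNA and depth are argued against by medians of -1.89 over 21 genes after subtraction of free RNA and -1.94 over 21 genes in thinned cells. For epithelial cells depth stays open, since the median was -0.12 (-0.76 to 0.27) in thinned cells. A single KPI animal is argued against as well: the neutrophil median was -2.15 in KPI cells with Y-linked and no Xist UMIs and -1.46 in those with Xist and no Y-linked UMIs, both against KP cells with Y-linked and no Xist UMIs. Whether 1 KP animal alone had high interferon genes cannot be told apart, because KP neutrophils held 0 Xist UMIs and gave no marker of the animal. Genotype, age and the state of single animals, such as an infection at sampling, stay open and untested.

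Rpl29, a ribosomal protein gene left out of naming and chosen after its values were seen, was between 5.91-fold and 7.11-fold higher in the KPI library in all 6 classes compared, and 14 of 5748 genes measured in all of them were at least 2-fold apart the same way in each. Free RNA is argued against by the lowest log2 ratio of the classes after its subtraction, 2.56. Reads shared with Rpl29 pseudogenes cannot be told apart, because the matrix had 0 pseudogene features of Rpl29 and the test is void. A germline variant or a strain difference near Rpl29 may account for such an even ratio: over all classes and over KPI cells with Y-linked or with Xist UMIs the log2 ratio ran from 2.30 to 2.92, but reads were not used here, so that it stays open, as do genotype and age.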
